A study of Mus musculus with 16 samples.

How the data were processed

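The deposited files hold, per the file headers, the spot intensity of each probe on a linear scale as written by Agilent Feature Extraction 11.0.1.1, with spatial detrending and background subtraction done inside that program; the submitters' processing notes name the same program. The authors also deposited a value table in log2 units, in which a higher value is a brighter probe and values are not centred per probe. It holds 9933 probes with values of r of at least 0.999 to the log2 intensity, and its normalization and choice of probes are not stated; 76.1% of its probes differ at least 2-fold between 2 groups. Its column medians were 6.595, 6.598, 6.615 and 6.609 for wild type vehicle, 6.473, 6.466, 6.493 and 6.469 for wild type TGF-β1, 6.586, 6.593, 6.567 and 6.58 for knockout vehicle, and 6.391, 6.38, 6.388 and 6.381 for knockout TGF-β1. Because the table is selected, the intensities of all probes were used, and these deposited values served as an alternative.

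Each array gave 59305 spots that are not controls, for 56605 probes, with 0 saturated spots. Intensities were log2 transformed, spots of a probe averaged, and each array shifted so that its 75th percentile matched. Within arrays, 300 probes with repeated spots had median SDs of 0.0316 to 0.0436. After 27 probes with outlier marks were left out, a probe was kept when it lay well above background on all 4 arrays of at least 1 group, which left 33888 probes. Of all probes 32994 received 1 of 22911 gene names by matching their transcript accession, without its version, to a reference of the mouse build GRCm38.p6. The array design was drawn on mm9, so no coordinates are given and the reference served only for names and gene order. Of kept probes 22709 were named and 11179 were not; the brightest probe over all arrays stood for each of 15394 genes, 5763 of which had several. Among 95 genes with several probes that the lists and the naming rule brought up, 18 had another probe at least 1 log2 unit away in a comparison of 2 groups. Levels were not compared between probes.

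Differences were tested with limma 3.58.1 in R 4.3.3, with files read by the data.table package, version 1.17.8. The model had 1 coefficient per group over all 16 arrays, empirical Bayes moderated spread, 2-sided tests and Benjamini-Hochberg adjustment over 15394 genes within each of 5 comparisons; adjusted p under 0.05 counted as changed. Values after ± are standard errors of log2 differences unless SD is given. The size of the response was the median interaction over genes called for the average effect of TGF-β1, signed so that positive means larger in knockout. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 25 lists within a comparison, and again with an estimated correlation. Camera asks whether a list shifted more than the other genes, so a list that did not pass can still hold many changed genes. The fry test, which asks whether a list changed at all, was planned beside it. It is given only for TGF-β targets in wild type cells. The 25 lists covered TGF-beta feedback and SMAD targets, contractile and myofibroblast genes, collagens, other matrix proteins, matrix proteases, lipofibroblast and adventitial markers, BMP signalling, cell cycle, cell cycle inhibitors, inflammatory and interferon-stimulated genes, stress response, glycolysis, cholesterol synthesis, NRF2 targets, YAP and TEAD targets, Wnt signalling, integrins, growth factors, and markers of macrophages, endothelium, epithelium, mesothelium and pericytes. Sex-linked genes, substrain-dependent genes and neighbours of Islr were given as values. List members not well above background on all arrays of any group were Bmp7, Ccne2, Cd79a, Col15a1, Cplx3, Csf2, Csf3, Cxcl9, Cyp11a1, Cyp1a1, Cyp1a2, Dkk1, Epcam, Hcn4, Islr2, Itgb8, Nkx2-1, Sftpa1, Slc7a10, Tbc1d21, Wif1 and Xist.

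Comparisons, lists, alternatives and the rule for naming genes were chosen before the data were examined, except the alternatives within 1 slide and the intensity column used for normexp. Named genes were Islr, then for each TGF-β1 and genotype comparison the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05 whose 4 arrays of one group all lay above or below the 4 of the other, and the 8 most positive and negative interactions. Symbols that are accessions, start with Gm or LOC, are of the AI, AU, AW, BC or BB type with digits, or end in Rik were passed over. Up to 4 list members with the smallest adjusted p could be named, and any member as a value. Normexp background correction, with an offset of 50, ran on the median spot signal because the files hold no mean spot signal.

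The fit was tested on simulated data with known changes added. It recovered 92.4% of 2-fold changes for TGF-β1 in wild type, 93.9% in knockout, 93.9% and 95.5% for genotype with vehicle and TGF-β1, and 89.4% for the interaction. For 1.25-fold changes recovery was 64.2%, 71.6%, 71.6%, 59.7% and 31.3%. Of the calls 2.96% to 6.57% were false, and 0 of 20 lists without a change had p under 0.05. The simulated noise was independent between genes and few genes were changed. The simulation therefore cannot show how often lists of correlated genes are called falsely.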

Results

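RNA levels were measured on 1-colour Agilent microarrays in primary lung fibroblasts of female-labelled mice, 8 weeks old. The cells lacked meflin, a membrane-anchored protein of fibroblasts encoded by Islr, or were wild type C57BL/6J, and each genotype was kept for 48 h without (vehicle) or with recombinant TGF-β1 at 5 ng/ml. TGF-β1 is the cytokine that turns fibroblasts into contractile, matrix-producing myofibroblasts. There were 16 arrays, 4 in each of the 4 groups, on 2 slides that each held 2 arrays of every group. The 75th percentile of spot intensity was 486 to 526 on the wild type vehicle arrays, 429 to 452 on the wild type TGF-β1 arrays, 470 to 519 on the knockout vehicle arrays and 382 to 446 on the knockout TGF-β1 arrays. Between 34251 and 35457, 32057 and 33556, 33300 and 34626, and 31308 and 32450 probes per array lay well above background in these groups, in the same order. Arrays of a group correlated with r of at least 0.99587 across the tested genes, and the median SD of a gene within a group was 0.0714 to 0.0856 log2 units. The first principal component held 82.3% of the variance and the second 8.48%. After filtering, 15394 genes were tested. Nothing ties the arrays to separate mice or cultures beyond the deposited design, which gives 4 independent experiments per group, so the p-values measure only the spread between these arrays, and 4 arrays per group limit the precision.

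The targeted gene was examined first. Islr stood at a log2 signal of 10.82 ± 0.06 (SD, n = 4) in wild type vehicle arrays and 8.34 ± 0.08 in wild type TGF-β1 arrays, well above background on all 8. In the knockout it was not well above background on any of 8 arrays, at 1.45 ± 0.16 with vehicle and 1.76 ± 0.07 with TGF-β1. It was therefore at least 138-fold lower in knockout cells with vehicle (adjusted p = 1.6e-19) and at least 19.7-fold lower with TGF-β1 (adjusted p = 6.33e-18). The vehicle bound was 134-fold within slide 1 and 142-fold within slide 2. TGF-β1 itself lowered Islr in wild type cells by 2.48 ± 0.07 (adjusted p = 2.6e-13). The array carries 1 probe for the gene, which could lie outside the deleted part.

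**Figure D1:**
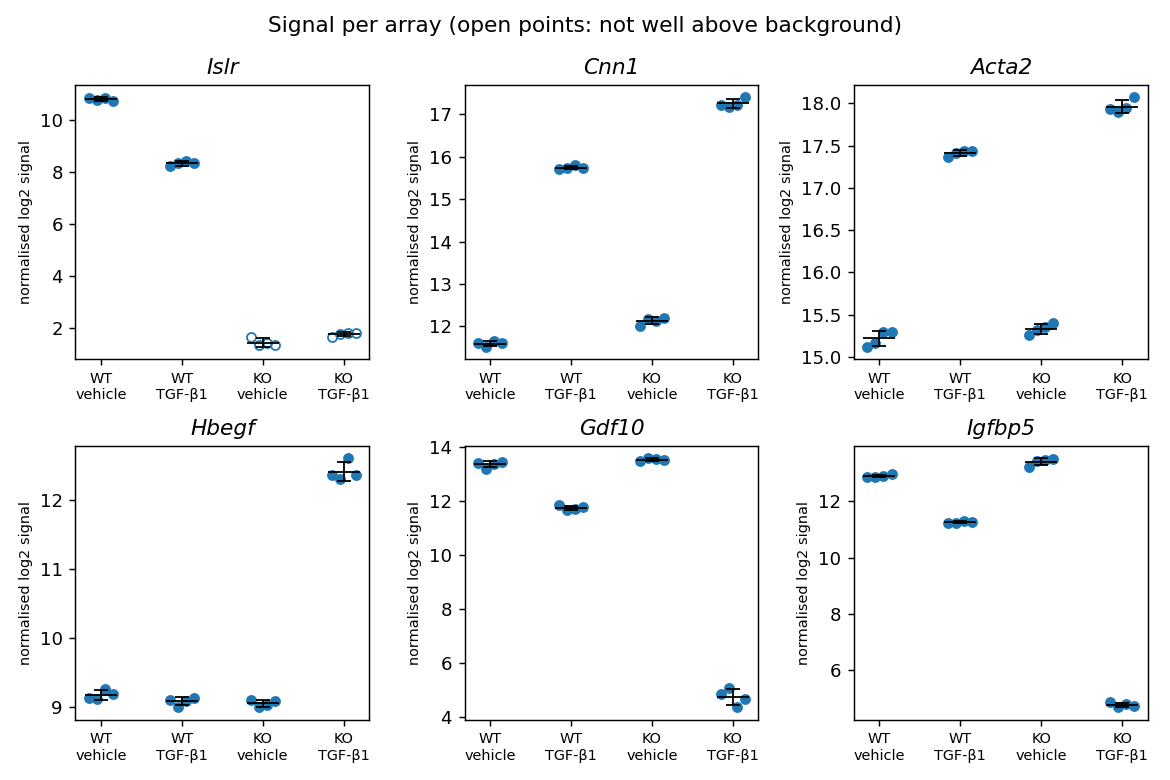
Normalized log2 signal (vertical axis) of Islr, Cnn1, Acta2, Hbegf, Gdf10 and Igfbp5 on each array (points; open where not well above background) of the 4 groups (horizontal axis), with group mean and SD as bars. Cnn1 went from 11.60 to 15.74 in wild type and from 12.13 to 17.25 in knockout cells, while Gdf10 fell to 11.75 and 4.73 and Hbegf was higher in the knockout TGF-β1 group alone.

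The comparison of TGF-β1 with vehicle in wild type cells asked which genes the cytokine alters in normal lung fibroblasts. Of 15394 genes 10560 changed (68.6%), 6360 upward and 4200 downward, with 502 rises and 993 falls of at least 2-fold. Rises made up 60.2% of the changed genes, against 52.1% with quantile normalization and 46.1% in the authors' value table. With the slide as a block 10817 genes changed, and 8448 and 9235 did within slides 1 and 2. The largest measured rises were in Wfdc21, a secreted antimicrobial-type protein (6.22 ± 0.12 SE, 74.6-fold, adjusted p = 8.46e-15), Arg1, the arginine-degrading enzyme arginase (5.57 ± 0.11, 47.6-fold), Cnn1, the smooth muscle protein calponin (4.15 ± 0.05, 17.7-fold), and Nt5e, the surface enzyme that makes adenosine from AMP (3.67 ± 0.09, 12.7-fold). The proteases Mcpt8 and Gzme rose at least 27.9-fold and 23-fold, with 3 and 1 of the 4 vehicle arrays well above background. Kcnmb1, a potassium channel subunit of smooth muscle, rose at least 11.4-fold and the peptide receptor Rxfp3 at least 2.51-fold from vehicle arrays that were all not well above background. Such bounds compare the mean of the brighter group with the dimmer group's mean, taking on each array the higher of the dim probe's own signal and the lowest signal among probes well above background.

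Most of the largest falls in wild type cells left genes at background. The carboxylesterase Ces1d fell at least 60.7-fold (adjusted p = 1.17e-13), the B cell chemokine Cxcl13 at least 34.5-fold, the angiotensin receptor Agtr2 at least 25.8-fold, and the secreted protein Scube1 at least 10.1-fold. Scara5, a ferritin receptor, fell at least 9.8-fold on its brightest probe, while a dimmer one changed by -0.82 log2 units. Ranbp3l, an inhibitor of nuclear SMAD signalling, fell at least 9.59-fold. Lgals2, a sugar-binding galectin, fell at least 38.1-fold with 2 of 4 TGF-β1 arrays above background.

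Among gene lists fixed in advance, that of contractile genes rose in wild type cells. Of 26 contractile and myofibroblast genes 24 rose and 1 fell, 25 of them passing when adjusted over the list alone. The median was 1.26 (adjusted p = 9.69e-11). Acta2, the smooth muscle actin of myofibroblasts, rose 2.19 ± 0.05 (1.76 and 2.59 on dimmer probes) and the sarcomeric actins Acta1 and Actc1 rose 2.81 ± 0.04 and 2.82 ± 0.04. The list's shift against all genes was 1.18 with the slide as a block, 1.24 within slide 1 and 1.16 within slide 2. Collagens split, with 12 rising, 6 falling and 3 not passing of 21 (18 adjusted over the list alone), a median of 0.38, or 0.30 with genes at background set to their bounds, and an adjusted p of 0.295. Col1a1, the main fibrillar collagen chain, rose 0.68 ± 0.04 and Col11a1 2.38 ± 0.05, Col6a1 of microfibrils fell by 1.20 ± 0.04, and Col3a1 stood at 0.30 ± 0.04 but at -0.05 with quantile normalization and in the authors' value table. Of 38 other matrix genes 27 rose and 8 fell (35 adjusted over the list alone). The matrix median was 0.56 (adjusted p = 0.00355, but adjusted p = 0.156 with an estimated correlation), with the crosslinking enzyme Loxl3 up 1.82 ± 0.06 and elastin (Eln) down by 1.68 ± 0.08 (-1.28 on a dimmer probe). Matrix proteases went both ways, 11 up and 10 down of 25 (21 adjusted over the list alone). The protease median was 0.00 (adjusted p = 0.967).

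Targets of TGF-β signalling itself did not pass as a list against the other genes in wild type cells, although most of them changed. Of 26 such genes 14 rose and 7 fell (21 adjusted over the list alone), with a median of 0.20 and an adjusted p of 0.231. Smad7, the feedback inhibitor, rose 0.55 ± 0.05, and the co-receptor Tgfbr3 fell by 0.65 ± 0.05. YAP and TEAD targets had 13 rises and 2 falls of 16 (15 adjusted over the list alone). The YAP and TEAD median was 0.38 (adjusted p = 0.00916, but adjusted p = 0.196 with an estimated correlation), led by Ankrd1, a nuclear mechanosensitive protein, at 1.98 ± 0.06. Of 27 BMP signalling genes 7 rose and 14 fell (21 adjusted over the list alone). The BMP median was -0.11, or -0.06 with bounds (adjusted p = 0.0286, but adjusted p = 0.17 with an estimated correlation), and the ligand Bmp4 was at -1.41 ± 0.07. Wnt signalling had 5 rises and 15 falls of 26 (20 adjusted over the list alone). The Wnt median was -0.34 (adjusted p = 0.00607, but adjusted p = 0.0917 with an estimated correlation). Growth factors and receptors had 10 rises and 16 falls of 31 (26 adjusted over the list alone). The growth factor median was -0.19 (adjusted p = 0.0226, but adjusted p = 0.238 with an estimated correlation). Integrins and adhesion genes had 10 rises and 5 falls of 23 (15 adjusted over the list alone). The integrin median was 0.11 (adjusted p = 0.121).

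Markers of resting lung fibroblasts went down in wild type cells. Of 19 lipofibroblast and alveolar fibroblast markers 15 fell and 2 rose (17 adjusted over the list alone). The lipofibroblast median was -1.02 (adjusted p = 3.43e-07), with falls in Adh1, an alcohol dehydrogenase (-3.41 ± 0.07), Pparg, the lipid-storage transcription factor (-1.74 ± 0.06), and the PDGF receptor Pdgfra (-0.44 ± 0.05). Of 19 adventitial and progenitor markers 15 fell and 3 rose (18 adjusted over the list alone). The adventitial median was -1.24 (adjusted p = 5.03e-06), with the stem cell antigen Ly6a at -2.07 ± 0.10 and the hyaluronan synthase Has2 up 1.80 ± 0.05.

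Most metabolic and growth lists had positive and the inflammatory lists negative medians in wild type cells. Glycolysis and hypoxia genes had 21 rises and 2 falls of 24 (23 adjusted over the list alone). The glycolysis median was 0.92 (adjusted p = 3.43e-07, but adjusted p = 0.0917 with an estimated correlation), with the lactate exporter Slc16a3 up 2.27 ± 0.05. Cell cycle genes had 34 rises and 1 fall of 37 (36 adjusted over the list alone). The cell cycle median was 0.50 (adjusted p = 3.43e-07, but adjusted p = 0.156 with an estimated correlation), and the mitotic kinase Aurka rose 1.02 ± 0.05. The unfolded protein and stress response list had 19 rises and 4 falls of 24 (23 adjusted over the list alone). The stress response median was 0.42 (adjusted p = 0.00136, but adjusted p = 0.196 with an estimated correlation), with asparagine synthetase (Asns) up 1.70 ± 0.05. Cholesterol and fatty acid synthesis had 17 falls and 1 rise of 25 (20 adjusted over the list alone). The cholesterol median was -0.28 (adjusted p = 9.78e-06, but adjusted p = 0.141 with an estimated correlation). The shift of this list against all genes, -0.35, was 0.28 in the authors' value table, where it did not pass (adjusted p = 0.766). NRF2 and oxidative stress genes had 13 falls and 3 rises of 20 (16 adjusted over the list alone). The NRF2 median was -0.47 (adjusted p = 0.000233). Cell cycle inhibitors had 10 rises and 6 falls of 19 (16 adjusted over the list alone; adjusted p = 0.967), with a median of 0.13, a mean of -0.21 and an upward test. Cdkn1c, an inhibitor of cyclin-dependent kinases, fell by 4.49 ± 0.05. Of 34 inflammatory genes 24 fell and 8 rose (32 adjusted over the list alone). The inflammatory median was -0.88 (adjusted p = 7.78e-06), with the eotaxin Ccl11 at -4.33 ± 0.07 and the neutrophil chemokine Cxcl1 at -2.76 ± 0.12. Interferon-stimulated genes had 26 falls and 1 rise of 31 (27 adjusted over the list alone). The interferon median was -0.75 (adjusted p = 3.51e-07, but adjusted p = 0.252 with an estimated correlation).

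Markers of other cell types were also measured in wild type cells. Macrophage and leukocyte markers had 15 falls and 1 rise of 19 (17 adjusted over the list alone). The macrophage median was -0.76 (adjusted p = 8.1e-07, but adjusted p = 0.17 with an estimated correlation), with the lysosomal protein Cd68 at -1.29 ± 0.06. Endothelial markers had 13 falls and 0 rises of 15 (13 adjusted over the list alone). The endothelial median was -0.97 (adjusted p = 1.13e-06), with von Willebrand factor (Vwf) at -1.85 ± 0.05. Epithelial markers had 5 falls and 3 rises of 13 (8 adjusted over the list alone). The epithelial median was -0.09, or -0.01 with bounds (adjusted p = 0.273). Mesothelial markers had 6 falls and 3 rises of 10 (9 adjusted over the list alone). The mesothelial median was -0.34 (adjusted p = 0.0605). Pericyte and smooth muscle markers had 7 rises and 6 falls of 15 (14 adjusted over the list alone; adjusted p = 0.967), with a median of -0.06, a mean of 0.22 and a downward test.

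The same treatment in knockout cells asked how fibroblasts without meflin respond. Here 12705 genes changed (82.5%), 7176 upward and 5529 downward, with 1472 rises and 2088 falls of at least 2-fold. The share of rises was 56.5%, against 48.6% with quantile normalization and 46.9% in the authors' value table, and the median over all genes was 0.10, against -0.01 with quantile normalization and -0.36 in the authors' value table. With the slide as a block 12846 genes changed, and 11355 and 12048 did within slides 1 and 2. Klhl30, a muscle-type adaptor protein, rose 41.5-fold (5.38 ± 0.10, adjusted p = 4.48e-16) and C1qtnf3, a secreted adipokine, 40.6-fold (5.35 ± 0.09, but 5.93 and 7.21 on dimmer probes). From vehicle arrays not well above background, Acan, the cartilage proteoglycan aggrecan, rose at least 18.4-fold, the keratin Krt20 at least 47.3-fold and Rxfp3 at least 19.4-fold. Mcpt8, Kcnmb1 and Gzme rose at least 62.1-fold, 41.7-fold and 42.2-fold, with 3, 1 and 1 of 4 vehicle arrays above background.

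In knockout cells Gdf10, a BMP-type growth factor, fell 448-fold (-8.81 ± 0.11, adjusted p = 1.39e-17), Igfbp5, a binding protein for insulin-like growth factors, 401-fold (-8.65 ± 0.06), Adamts15, a protease of proteoglycans, 164-fold (-7.36 ± 0.13) and the neutrophil chemokine Cxcl5 163-fold (-7.35 ± 0.11). Sfrp2, a secreted Wnt regulator, fell at least 196-fold with 2 of 4 TGF-β1 arrays above background. Scrg1, a small secreted protein of mesenchymal cells, fell at least 90.2-fold, the steroid sulfate carrier Slc10a6 at least 55.7-fold and Ces1d at least 52-fold, all to background.

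The contractile list rose in knockout cells too. Of 26 contractile genes 25 rose and 1 fell (26 adjusted over the list alone). The contractile median was 2.19 (adjusted p = 6.16e-09), with Cnn1 up 5.12 ± 0.05, Acta1 4.32 ± 0.04 and Acta2 2.63 ± 0.05 (2.82 and 4.17 on dimmer probes), and the list's shift was 2.09 with the slide as a block, 2.08 within slide 1 and 2.13 within slide 2. TGF-β targets had 21 rises and 4 falls of 26 (25 adjusted over the list alone). The TGF-β target median was 0.94 (adjusted p = 0.00143, but adjusted p = 0.152 with an estimated correlation), with the ligands Tgfb2 and Tgfb3 up 1.61 ± 0.06 and 1.62 ± 0.05. YAP and TEAD targets had 14 rises and 2 falls of 16 (16 adjusted over the list alone). The YAP and TEAD median was 0.94 (adjusted p = 0.000724, but adjusted p = 0.14 with an estimated correlation), with Ankrd1 up 5.03 ± 0.06 and the matricellular protein Ccn2 up 2.41 ± 0.08. Other matrix genes had 28 rises and 7 falls of 38 (35 adjusted over the list alone). The matrix median was 0.86 (adjusted p = 0.00373, but adjusted p = 0.0564 with quantile normalization and adjusted p = 0.152 with an estimated correlation), and Postn, the matricellular protein periostin, rose 2.62 ± 0.06. Collagens had 14 rises and 7 falls of 21 (21 adjusted over the list alone). The collagen median was 0.57 (adjusted p = 0.225), with Col1a1 up 0.74 ± 0.04 and the anchoring fibril collagen Col7a1 up 2.75 ± 0.06.

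Fibroblast identity markers also fell in knockout cells. Of 19 lipofibroblast markers 16 fell and 2 rose (18 adjusted over the list alone; adjusted p = 1.8e-06), with a median of -2.46, or -2.26 with genes at background set to their bounds. Pdgfra was at -2.21 ± 0.05 and Fgf10, a growth factor for epithelium, at -2.86 ± 0.06 (-1.61 on a dimmer probe). Of 19 adventitial markers 16 fell and 3 rose (19 adjusted over the list alone). The adventitial median was -1.61 (adjusted p = 8.09e-05), with Ly6a at -5.89 ± 0.10 and the peptidase Dpp4 at -3.21 ± 0.05. Wnt signalling had 16 falls and 8 rises of 26 (24 adjusted over the list alone). The Wnt median was -0.68 (adjusted p = 0.019, but adjusted p = 0.126 with quantile normalization and adjusted p = 0.14 with an estimated correlation). BMP signalling had 15 falls and 8 rises of 27 (23 adjusted over the list alone). The BMP median was -0.38 (adjusted p = 0.0424, but adjusted p = 0.0842 with quantile normalization, 0.0532 with the slide as a block and adjusted p = 0.184 with an estimated correlation).

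Glycolysis genes had 21 rises and 2 falls of 24 in knockout cells (23 adjusted over the list alone). The glycolysis median was 1.56 (adjusted p = 2.47e-06, but adjusted p = 0.14 with an estimated correlation), with hexokinase (Hk2) up 2.27 ± 0.06. Cell cycle genes had 34 rises and 1 fall of 37 (35 adjusted over the list alone). The cell cycle median was 0.75 (adjusted p = 1.8e-06, but adjusted p = 0.158 with an estimated correlation). Stress response genes had 20 rises and 4 falls of 24 (24 adjusted over the list alone). The stress response median was 0.66 (adjusted p = 0.00143, but adjusted p = 0.195 with an estimated correlation). NRF2 genes had 13 falls and 4 rises of 20 (17 adjusted over the list alone). The NRF2 median was -0.44 (adjusted p = 0.0116, but adjusted p = 0.14 with an estimated correlation). Inflammatory genes parted, in that 22 fell and 10 rose of 34 (32 adjusted over the list alone). The inflammatory median was -1.23, or -1.06 with bounds (adjusted p = 0.00109, but adjusted p = 0.106 with an estimated correlation), with Cxcl1 and the acute phase protein Saa3 at -6.69 ± 0.12 and -6.07 ± 0.11, and the cytokines Il11 and Lif up 2.89 ± 0.13 and 2.22 ± 0.10. Interferon-stimulated genes had 27 falls and 1 rise of 31 (28 adjusted over the list alone). The interferon median was -1.42 (adjusted p = 4.36e-07, but adjusted p = 0.252 with an estimated correlation).

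Among other cell types in knockout cultures, macrophage markers had 16 falls and 2 rises of 19 (18 adjusted over the list alone). The macrophage median was -1.01 (adjusted p = 8.19e-05, but adjusted p = 0.235 with an estimated correlation). Endothelial markers had 14 falls and 1 rise of 15 (15 adjusted over the list alone). The endothelial median was -1.07 (adjusted p = 8.09e-05). Mesothelial markers had 8 falls and 1 rise of 10 (9 adjusted over the list alone). The mesothelial median was -1.59 (adjusted p = 0.00143, but adjusted p = 0.118 with an estimated correlation), with the uroplakin Upk3b at -3.35 ± 0.08 and the membrane glycoprotein Gpm6a at -3.89 ± 0.09. The remaining 8 lists, counting collagens, had adjusted p of 0.225 to 0.839. In these the median, mean and test of the protease list (-0.15, 0.07 and downward), of the cell cycle inhibitors (0.27, -0.53 and upward) and of the epithelial markers (0.10, -0.83 and downward) differed in sign.

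**Figure D2:**
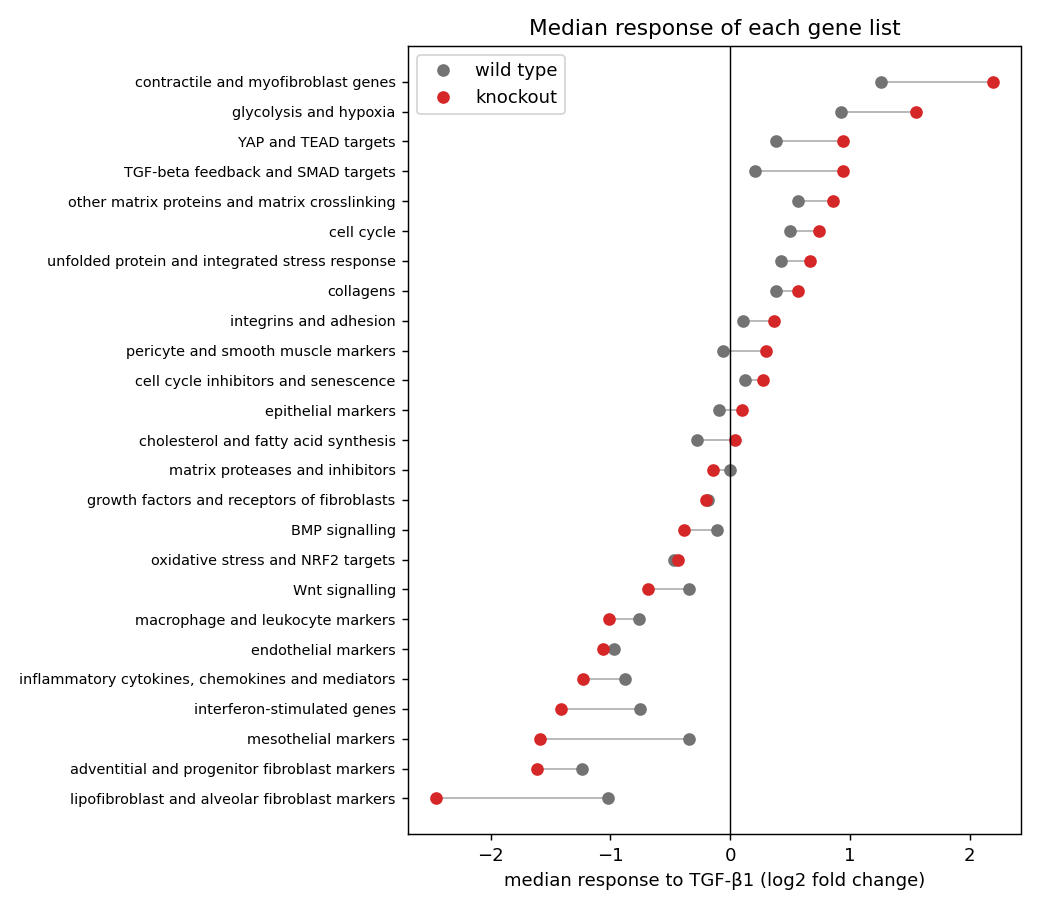
Median log2 response to TGF-β1 (horizontal axis) of each of the 25 gene lists (vertical axis) in wild type (grey) and knockout cells (red). The medians reach from -1.24 to 1.26 in wild type and from -2.46 to 2.19 in knockout cells. The wild type median of cholesterol and fatty acid synthesis was -0.28, a shift of -0.35 against the median of all genes. In the authors' value table that shift was 0.28 (adjusted p = 0.766 with camera).

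The genotypes were compared without TGF-β1 to ask how untreated knockout and wild type cultures differ. With vehicle 2037 genes differed (13.2%), 1089 higher and 948 lower in knockout, and at least 2-fold differences numbered 10 and 38. Higher genes made up 53.5%, against 38.8% in the authors' value table, 27.7% within slide 1 and 36.2% within slide 2. With the slide as a block 2392 genes differed, but 184 within slide 1 and 1006 within slide 2. Apart from Islr, Lrmda, a melanocyte differentiation protein, was 3.69-fold lower (-1.88 ± 0.05, adjusted p = 3.46e-12), Clec1b, a lectin receptor of platelets, 3.02-fold (-1.59 ± 0.07), Plac9a, a small secreted protein, 2.91-fold (-1.54 ± 0.06), Tmem254a, a membrane protein, 2.66-fold (-1.41 ± 0.06), the carboxylesterase Ces2b 2.53-fold (-1.34 ± 0.20) and the T cell adhesion protein Cd2 2.51-fold (-1.33 ± 0.07). Syt10, a vesicle protein, was at least 6.8-fold lower with 2 of 4 knockout arrays above background. Higher in knockout were the prolactin relative Prl3a1 (2.18-fold, 1.13 ± 0.08, adjusted p = 6.67e-07), Efcab7, a protein of cilia (2.15-fold), and Arg1 (2.14-fold). Jchain, which joins antibody units, and the acute phase protein Saa4 were at least 2.47-fold and 1.63-fold higher than background. The pseudogene Tmem181b-ps was at least 2.37-fold higher with 1 of 4 wild type arrays above background, and Lrrn1, a neuronal membrane protein, at least 1.73-fold with 2 of 4. For the natriuretic peptide Nppb the direction stayed open, since the probe used was at least 1.36-fold higher with 3 of 4 knockout arrays above background, a call lost with normexp background correction, and another probe stood at -0.31.

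List shifts with vehicle were small. Contractile genes had 5 higher and 0 lower of 26 in knockout (10 adjusted over the list alone). The contractile median was 0.10 (adjusted p = 0.00286, but adjusted p = 0.27 with an estimated correlation), with Cnn1 higher by 0.54 ± 0.05. Adventitial markers had 9 lower and 2 higher of 19 (11 adjusted over the list alone). The adventitial median was -0.13 (adjusted p = 0.00284). Mesothelial markers had 5 lower and 0 higher of 10 (7 adjusted over the list alone). The mesothelial median was -0.19 (adjusted p = 4.22e-06). Macrophage markers had 9 lower and 0 higher of 19 (13 adjusted over the list alone). The macrophage median was -0.22 (adjusted p = 2.54e-12, but adjusted p = 0.132 with an estimated correlation), with the integrin Itgax, the scavenger receptor Marco and lysozyme (Lyz2) lower by 0.94 ± 0.06, 0.90 ± 0.08 and 0.56 ± 0.07. The macrophage shift was -0.25 with the slide as a block, -0.19 within slide 1 and -0.39 within slide 2. RNA of whole cultures cannot tell fewer cells with these markers from lower expression in each cell. Inflammatory genes had 11 lower and 1 higher of 34 (19 adjusted over the list alone). The inflammatory median was -0.14 (adjusted p = 0.000191, but adjusted p = 0.0707 with an estimated correlation). Interferon-stimulated genes had 7 lower and 0 higher of 31 (9 adjusted over the list alone). The interferon median was -0.26 (adjusted p = 5.38e-08, but adjusted p = 0.398 with an estimated correlation), and their shift was 0.01 within slide 1 and -0.52 within slide 2. Endothelial markers had 2 lower and 0 higher of 15 (2 adjusted over the list alone). The endothelial median was -0.07 (adjusted p = 0.0245, but adjusted p = 0.26 within slide 1 and adjusted p = 0.227 with an estimated correlation). The other 18 lists had adjusted p of 0.0503 to 0.759, and among them the protease list (median 0.02, mean 0.02) and the stress response list (median 0.00, mean -0.04) tested downward.

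The genotypes were also compared under TGF-β1, which asks where the treated cells end up apart. Here 10800 genes differed (70.2%), 6099 higher and 4701 lower in knockout, with 510 and 1080 at least 2-fold. Higher genes made up 56.5%, against 46.8% with quantile normalization and 47.1% in the authors' value table, and 11047 genes differed with the slide as a block, 8388 within slide 1 and 9783 within slide 2. Lower in knockout were Gdf10 (130-fold, -7.02 ± 0.11, adjusted p = 7.75e-16), Adamts15 (94.4-fold), Igfbp5 (89.8-fold), the hemoglobin-binding protein Hp (51.6-fold, -5.69 ± 0.08) and Angptl7, a secreted angiopoietin-like protein (48.8-fold). Slc10a6 and the neuropeptide gene Calca were at least 24.1-fold and 10.4-fold lower, at background in knockout. Higher were Acsbg1, which activates fatty acids (17.7-fold, 4.14 ± 0.22, adjusted p = 3.25e-10), C1qtnf3 (12.6-fold) and the serotonin receptor Htr2b (11.7-fold). The chemokine Ccl17, the aldo-keto reductase Akr1c19, the sialyltransferase St8sia2, the skin barrier protein Lce1f and the galactosyltransferase B3galt5 were at least 13.7-fold, 8.97-fold, 8.01-fold, 6.74-fold and 4.48-fold higher, each not well above background in treated wild type cells.

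Contractile genes were higher in treated knockout cells for 24 and lower for 2 of 26 (26 adjusted over the list alone). The contractile median was 0.84 (adjusted p = 6.73e-08, but adjusted p = 0.0523 with an estimated correlation). Their shift was 0.78 with the slide as a block, 0.78 within slide 1 and 0.79 within slide 2. TGF-β targets were higher for 22 and lower for 2 of 26 (25 adjusted over the list alone). The TGF-β target median was 0.68 (adjusted p = 1.13e-05, but adjusted p = 0.0971 with an estimated correlation), with Pmepa1, which restrains the pathway, higher by 1.29 ± 0.03. Cholesterol synthesis genes were higher for 22 and lower for 0 of 25 (22 adjusted over the list alone). The cholesterol median was 0.47 (adjusted p = 5.12e-06, but adjusted p = 0.106 with an estimated correlation). Glycolysis, YAP and TEAD, cell cycle, stress response and other matrix genes also had higher medians, 0.29 to 0.61, with adjusted p of 5.12e-06 to 0.028. Each of these 5 calls was lost with an estimated correlation (adjusted p = 0.104 to 0.328), and those of the stress response and other matrix genes also with quantile normalization (both 0.168). Elastin was higher by 2.29 ± 0.08 (2.72 on a dimmer probe).

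Lipofibroblast markers were lower in treated knockout cells for 15 and higher for 2 of 19, 17 adjusted over the list alone (adjusted p = 1.13e-05), with a median of -0.99, or -0.65 with bounds. Mesothelial markers were lower for 8 and higher for 2 of 10 (10 adjusted over the list alone). The mesothelial median was -1.57 (adjusted p = 0.000299, but adjusted p = 0.0971 with an estimated correlation). Interferon-stimulated genes were lower for 26 and higher for 1 of 31 (28 adjusted over the list alone). The interferon median was -0.99 (adjusted p = 1.03e-06, but adjusted p = 0.317 with an estimated correlation). Adventitial, inflammatory, macrophage and endothelial genes had medians of -0.36 to -0.71 with adjusted p of 0.000389 to 0.0233. The inflammatory median was -0.35 with bounds. These 4 calls were lost with an estimated correlation (adjusted p = 0.0971 to 0.317), and those of the adventitial and endothelial genes also with quantile normalization (both 0.0592). The other 10 lists had adjusted p of 0.167 to 0.909. Median, mean and test differed in sign for cell cycle inhibitors (0.01, -0.29 and downward) and growth factors (0.13, -0.02 and upward).

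The interaction of genotype and treatment asked whether the response to TGF-β1 differs between knockout and wild type cultures. The response differed for 8967 of 15394 genes (58.2%), of which 7843 responded more in knockout and 1124 more in wild type. The difference was positive for 4887 and negative for 4080, or 54.5% positive, against 43.6% with quantile normalization and 48.1% in the authors' value table. With the slide as a block 9348 genes differed, 5570 within slide 1 and 7838 within slide 2. Over the 12864 genes called for the average effect of TGF-β1, the median response was larger in knockout by 0.28 log2 units, or 1.21-fold, 0.25 for 7414 rising and 0.35 for 5450 falling genes, and 81.8% of these genes responded more in knockout. That median was 0.28 with the slide as a block, 0.29 within slide 1 and 0.31 within slide 2. Across genes, which are not independent replicates, the responses of both genotypes correlated with r = 0.813 and rho = 0.809. There were 5391 genes up in both genotypes (2965 if independent), 3610 down in both (1508 if independent), 383 up in wild type and down in knockout, and 225 the reverse, 8 of these 608 at least 2-fold in both. Of genes changed at least 2-fold in either genotype, 3332 of 3742 changed more in knockout.

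Of single genes, Gdf10 had the most negative interaction (-7.20 ± 0.16 SE, n = 4 per group, adjusted p = 9.53e-14), falling by 1.61 in wild type and 8.81 in knockout, followed by Igfbp5 (-7.00 ± 0.08) and Adamts15 (-6.87 ± 0.18) among genes well above background on all arrays. Hp (-6.08 ± 0.11) and Angptl7 (-5.19 ± 0.11) rose in wild type cells by 0.76 and 0.57 and fell in knockout cells. Chl1, a neural adhesion protein (-5.29 ± 0.35 on the brightest probe, -3.28 and -0.78 on 2 others), the hair keratin partner Krtap11-1 (-5.20 ± 0.34) and Slc10a6 (-6.63 ± 0.08) reached background in treated knockout cells, so the size of these 3 fitted differences is uncertain. Acsbg1 had a positive interaction of 4.46 ± 0.31 (adjusted p = 1.72e-08). Akr1c19 (5.26 ± 0.49), Ccl17 (4.53 ± 0.49), Lce1f (3.97 ± 0.50), B3galt5 (3.92 ± 0.23), the collagen-binding surface protein Lrrc15 (3.84 ± 0.56), the small heat shock protein Hspb3 (3.62 ± 0.49) and Rgs4, a brake on G protein signalling (3.59 ± 0.38), were well above background on all 4 arrays of the knockout TGF-β1 group and at background in treated wild type cells, so the size of these fitted differences is uncertain too.

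Growth factor genes parted between the genotypes, with 13 positive and 12 negative interactions of 31 (25 adjusted over the list alone; adjusted p = 0.945; median 0.05, mean -0.07, downward test). The EGF receptor ligand Hbegf stood at -0.09 ± 0.06 in wild type and rose 3.36 ± 0.06 in knockout (interaction 3.45 ± 0.08, adjusted p = 2.88e-13), and neuregulin (Nrg1) fell by 1.42 and rose by 1.16 on its brightest probe (-1.87 and -0.79, and 0.95 and 2.57, on 2 others). The lymphatic growth factor Vegfd fell in both (interaction -4.12 ± 0.11, adjusted p = 6.38e-13). Inflammatory genes had 20 negative and 11 positive interactions of 34 (31 adjusted over the list alone). The inflammatory median was -0.43 (adjusted p = 0.0191, but adjusted p = 0.0834 with quantile normalization and adjusted p = 0.176 with an estimated correlation), among them Il11 (3.14 ± 0.18), Lif (2.93 ± 0.14) and cyclooxygenase Ptgs2 (2.52 ± 0.09) on the positive and Saa3 (-4.38 ± 0.15) and Cxcl1 (-3.94 ± 0.17) on the negative side.

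Contractile genes had 24 positive and 2 negative interactions of 26 (26 adjusted over the list alone). The contractile median was 0.75 (adjusted p = 2.59e-08), with Acta1 at 1.51 ± 0.06, Cnn1 at 0.97 ± 0.07 and Acta2 at 0.44 ± 0.07. Dimmer probes gave 1.51 for Cnn1 and 1.06 and 1.58 for Acta2. The list's shift was 0.70 with the slide as a block, 0.70 within slide 1 and 0.67 within slide 2. TGF-β targets had 21 positive and 2 negative of 26 (23 adjusted over the list alone). The TGF-β target median was 0.68 (adjusted p = 1.52e-05, but adjusted p = 0.118 with an estimated correlation), with the ligand Tgfb3 at 1.16 ± 0.08 and Tgfbr3 at -2.11 ± 0.07. YAP and TEAD targets had 11 positive and 0 negative of 16 (12 adjusted over the list alone). The YAP and TEAD median was 0.51 (adjusted p = 0.000168, but adjusted p = 0.118 with an estimated correlation), with Ankrd1 at 3.05 ± 0.08. Other matrix genes had 19 positive and 9 negative of 38 (28 adjusted over the list alone). The matrix median was 0.32 (adjusted p = 0.0371, but adjusted p = 0.239 with quantile normalization and adjusted p = 0.294 with an estimated correlation), with Has2, a member of another list, at 2.79 ± 0.07 and elastin at 2.13 ± 0.12 (2.81 on a dimmer probe). Collagens had 10 positive and 7 negative of 21 (17 adjusted over the list alone). The collagen median was 0.10 (adjusted p = 0.403), with Col7a1 at 1.85 ± 0.08, Col3a1 at -0.84 ± 0.06, and Col1a1 at 0.06 ± 0.06 but at -0.18 with quantile normalization.

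Glycolysis genes had 22 positive and 1 negative interactions of 24 (24 adjusted over the list alone). The glycolysis median was 0.57 (adjusted p = 2.5e-06, but adjusted p = 0.126 with an estimated correlation). Cholesterol synthesis had 20 positive and 0 negative of 25 (21 adjusted over the list alone). The cholesterol median was 0.38 (adjusted p = 8.52e-06, but adjusted p = 0.126 with an estimated correlation). Cell cycle genes had 20 positive and 1 negative of 37 (21 adjusted over the list alone). The cell cycle median was 0.20 (adjusted p = 0.000977, but adjusted p = 0.358 with an estimated correlation). Stress response genes had 16 positive and 2 negative of 24 (19 adjusted over the list alone). The stress response median was 0.29 (adjusted p = 0.00729, but adjusted p = 0.0862 with quantile normalization and adjusted p = 0.294 with an estimated correlation). Lipofibroblast markers had 13 negative and 2 positive of 19 (17 adjusted over the list alone). The lipofibroblast median was -1.01 (adjusted p = 3.69e-05), with Pdgfra at -1.77 ± 0.07 and the alveolar transcription factor Tcf21 at -1.06 ± 0.08. Adventitial markers had 10 negative and 5 positive of 19 (15 adjusted over the list alone). The adventitial median was -0.49 (adjusted p = 0.0371, but adjusted p = 0.114 with quantile normalization, 0.0697 within slide 1 and adjusted p = 0.118 with an estimated correlation). Interferon-stimulated genes had 21 negative and 1 positive of 31 (22 adjusted over the list alone). The interferon median was -0.74 (adjusted p = 0.000464, but adjusted p = 0.477 with an estimated correlation). Mesothelial markers had 7 negative and 2 positive of 10 (9 adjusted over the list alone). The mesothelial median was -1.47 (adjusted p = 0.000977, but adjusted p = 0.118 with an estimated correlation). Endothelial markers had 8 negative and 1 positive of 15 (9 adjusted over the list alone). The endothelial median was -0.42 (adjusted p = 0.0285, but adjusted p = 0.157 with quantile normalization, 0.137 with normexp background correction and adjusted p = 0.176 with an estimated correlation). The other 10 lists, counting collagens and not growth factors, had adjusted p of 0.0739 to 0.945. The median, mean and test of the proteases (0.19, -0.21 and downward), of cell cycle inhibitors (0.02, -0.33 and downward) and of epithelial markers (0.12, -0.06 and upward) differed in sign.

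**Figure D3:**
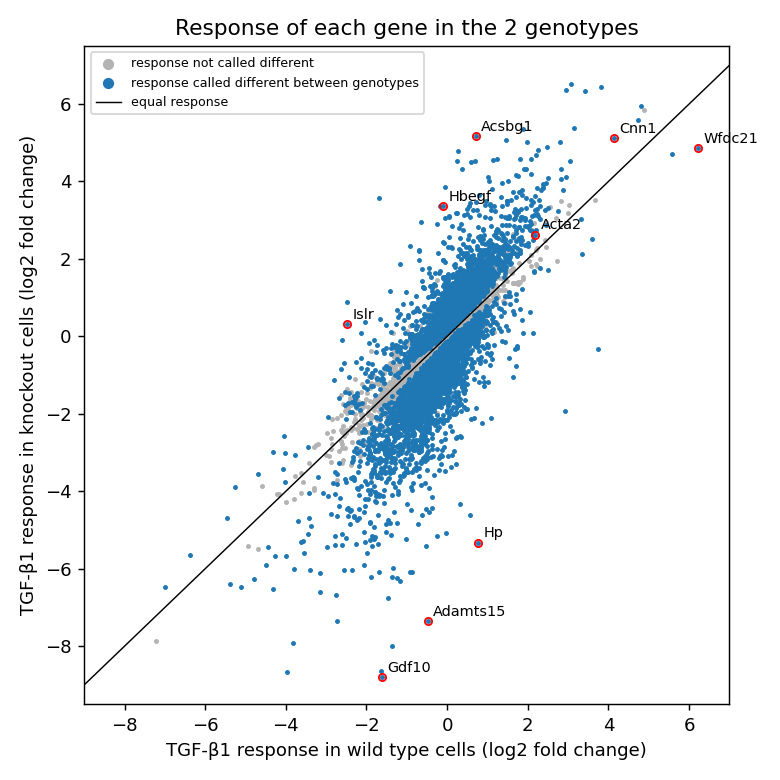
Log2 response to TGF-β1 in wild type (horizontal axis) against knockout cells (vertical axis) of each of 15394 genes (points; blue where the response differed between genotypes, line of equal response in black), with a few genes named. Gdf10 lies at -1.61 and -8.81, Hbegf at -0.09 and 3.36, and Acsbg1 at 0.71 and 5.17, and the axis through the cloud has a slope of 1.84.

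Of 125 list tests 70 passed with the preset correlation, 69 with the slide as a block, 69 within slide 1 and 72 within slide 2. With an estimated correlation 15 passed: in wild type cells contractile, lipofibroblast, adventitial, inflammatory, NRF2 and endothelial genes; in knockout cells contractile, lipofibroblast, adventitial and endothelial genes; with vehicle adventitial and mesothelial markers; between treated genotypes lipofibroblast markers; and for the interaction contractile and lipofibroblast genes.

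Genes that check the labels were measured on every array. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y were well above background on 16 of 16 arrays and Xist, the RNA that silences an X chromosome in female cells, on 0 of 16 with its single probe, although the arrays are labelled female. A further Kdm5d probe was well above background on 0 of 16 arrays. Of genes that differ between C57BL/6 substrains, the nucleotidase Entpd4 was lower in knockout with vehicle by 0.69 ± 0.03 (adjusted p = 1.06e-08), the insulin-degrading enzyme Ide by 0.31 ± 0.05 (adjusted p = 0.000671), and Wdfy1, an endosomal protein, stood at 0.00 ± 0.04 (adjusted p = 0.994), while Nnt was not measured. Of 19 measured neighbours of Islr, the netrin receptor Neo1 (0.18 ± 0.05, adjusted p = 0.0263, but 0.0518 with quantile normalization) and the kinase Csk (-0.16 ± 0.05, adjusted p = 0.0435, but 0.03 on a dimmer probe) differed with vehicle.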

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

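The tests of brightness, of a single factor and of the labels were chosen only after the result was seen, and the comparisons with other splits of the arrays were not.

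Some values lay far from the other 3 of their group, measured as the gap to the nearest array over the range of the group. Chance gives such a value in about 1 in 20 groups, and 14 of 255 groups had one (5.49%). The 75th percentile of log2 signal was 9.02 on replicate 4 of the knockout vehicle group against 8.88 to 8.90 on the others (gap over range 0.855). Among genes, Acsbg1 was low on replicate 1 of wild type vehicle (3.97 against 4.74 to 4.89, 0.831), Gzme and Lrmda on replicate 1 of wild type TGF-β1 (8.13 against 8.26 to 8.27, 0.921, and 10.07 against 10.13 to 10.14, 0.901), and Jchain on replicate 1 of knockout vehicle (4.43 against 5.05 to 5.14, 0.866). In the knockout TGF-β1 group Nppb was low on replicate 2 (6.69 against 7.24 to 7.32, 0.875), Plac9a on replicate 1 (11.72 against 11.90 to 11.93, 0.88) and Rgs4 on replicate 4 (6.23 against 6.55 to 6.58, 0.896). Sfrp2 was high on replicate 2 of wild type vehicle (11.90 against 11.76 to 11.78, 0.877). Among means of gene lists, inflammatory genes were high on replicate 3 of wild type TGF-β1 (10.08 against 10.02, 0.951) and interferon-stimulated genes on replicate 1 of knockout vehicle (10.24 against 10.11 to 10.13, 0.895). Glycolysis genes were low on replicate 1 of knockout vehicle (12.68 against 12.72, 0.831), NRF2 genes on replicate 2 of wild type vehicle (11.68 against 11.72, 0.864) and endothelial markers on replicate 3 of knockout TGF-β1 (7.10 against 7.22 to 7.24, 0.841).

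The response to TGF-β1 differed between genotypes by the interaction test for 8967 genes and 14 of 25 gene lists, 2 of them with an estimated correlation, and was larger in knockout by a median of 0.278 log2 units. Array brightness that differed between the groups would shift rising and falling genes in opposite directions, but with quantile normalization the response stayed larger in knockout by 0.2 for rising and 0.3 for falling genes, and both stayed at 0.194 or more with any array left out. A single factor multiplying 1 common response would leave no gene with opposite responses, yet 152 of 5415 genes that changed in both genotypes by at least the smallest fold of the simulated data went opposite ways after centring (2.81%, and 2.64% to 2.88% with any array left out). Animals or cultures that differed between the groups cannot be told apart from genotype, because 0 arrays carry a label naming the animal or culture. Genetic background cannot be told apart from loss of meflin either. The substrain-dependent genes Entpd4 and Ide were lower in knockout with vehicle, while Wdfy1 was not on its brightest probe (-0.25 and 0.07 on 2 others). A larger response of the knockout cultures may be biological, without being tied to loss of meflin, and it was found and tested on the same data.

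Other splits of the same arrays were fitted to see whether chance groupings give as much. For the counts of genes 1 of 35 splits, the real one, gave as many for TGF-β1 in wild type (10560 against at most 1 in any other) and in knockout (12705 against 1). The same held for genotype with vehicle (2037 against 4) and with TGF-β1 (10800 against 2). This is the smallest share that 35 splits can give. The other splits mix the groups, whose difference widens the spread and keeps their counts low, so they cannot exclude chance. For the interaction 2 of 100 splits reached the real 8967, and the other, with 9691, swapped whole genotype groups within 1 treatment, which is a structure of the samples, while splits that mixed groups gave at most 86. For the response size (0.278) 2 of 100 splits were as far from 0. The other of these was the same swap of whole groups, 0.344 in size and negative, and the 98 splits that mixed groups reached at most 0.203. For the interaction, splits regroup genotypes within each treatment. They therefore test for any genotype difference and cannot single out a difference in response. Splits that followed the slides called 0, 1, 0 and 0 genes. Each side of such a split holds arrays of both groups, whose difference widens the spread, so these counts cannot exclude an effect of the slide. For the number of lists, no other split reached the real count for genotype with TGF-β1 (15 against 13, 1 of 35). That too is weak evidence, since splits exchanging 1 array per group called up to 13 lists, and those exchanging 2 at most 1. For the interaction (14 against 14; 2 of 100) the number of lists is weak evidence, since 42 of the 98 splits that mixed groups called 8 lists or more, up to 13. Chance cannot be excluded for TGF-β1 in wild type (17 against 17; 3 of 35), in knockout (17 against 17; 4 of 35) or genotype with vehicle (7 against 9; 6 of 35), where splits exchanging 1 array per group keep part of the real contrast and splits exchanging 2 gave at most 2, 2 and 6 lists.

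Probes without a gene name, which no comparison used, also carried signal. Of 11179 such probes 5647 changed with TGF-β1 in wild type cells (50.5%), 8128 in knockout cells (72.7%), 262 differed by genotype with vehicle (2.34%) and 5678 with TGF-β1 (50.8%), and 3857 had a different response (34.5%). No explanation was tested for these.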

How the results depend on the processing

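The alternatives within 1 slide, and the use of the median spot signal for normexp, were chosen after the data were seen. Counted once for each gene, comparison and alternative, 19282 gene values kept direction and call, 416 lost a call, 120 gained one, 164 without a call moved and 21 reversed; for list shifts these were 2719, 108, 37, 60 and 1. With 4 arrays per group, leaving out each array in turn gave 10121 to 10355 genes for TGF-β1 in wild type, 12401 to 12559 in knockout, 1484 to 2050 for genotype with vehicle, 10359 to 10612 with TGF-β1, 8609 to 9045 for the interaction, a response size of 0.272 to 0.287, 69 to 72 lists, and Islr at least 134-fold to 146-fold lower in knockout with vehicle. The replicate number used as a block gave 10791, 12842, 2301, 11061 and 9308 genes, 69 lists and a response size of 0.275. With it the BMP list in knockout cells (adjusted p = 0.0537) and the interactions of the other matrix (0.067) and adventitial lists (0.0507) no longer passed, while the BMP (0.0486) and cell cycle lists (0.0492) passed with vehicle. The numbers were not taken as pairs in the main fit, because the labels tie them to no animal. Of 24 pairs with the same number 8 correlated above 0.1 (-0.034 to 0.218). Yet in 17 of 24 such comparisons an array correlated best with its own number, more often than the 1 in 4 that unrelated numbers would give. All 4 pairs of wild type TGF-β1 and knockout vehicle arrays exceeded 0.1. Some numbers therefore share structure that the main fit leaves out. Replicates 1 and 2 of every group lay on slide 1 and replicates 3 and 4 on slide 2. The fourth principal component, with 1.27% of the variance, was negative on every slide 1 array (-16.4 to -1.8) and positive on every slide 2 array (3.2 to 11.9). The arrays therefore differed with the slide to a small extent. Whether the slide itself or a day or culture shared within it lies behind this stays open. Named genes with fewer than 4 arrays of the dimmer group well above background were limited by signal, and their folds are bounds.

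In the authors' value table, which holds 5255 of the genes, fewer were tested and 4376, 4841, 1158, 4214 and 3827 passed in the same order. Within slide 1, with fewer arrays, 184 genes differed by genotype with vehicle and 5570 for the interaction, and within slide 2 1006 did with vehicle. With an estimated correlation 15 lists passed in place of 70, and quantile normalization gave 59, normexp 71, no filter 77, a filter on all arrays 67, the mean over probes 71, trend and robust 70, array weights 71 and the values deposited by the authors 49. Changes of at least 2-fold fell in number with normexp, whose offset shrinks folds, from 1495, 3560, 48, 1590 and 1533 to 736, 2123, 11, 756 and 710.

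The cause of the following reversals was not tested. With quantile normalization TGF-β1 in wild type gave Col3a1 -0.048 (0.302 otherwise), Entpd4 -0.111 (0.02) and Plaur -0.164 (0.001), and in knockout Plin2 -0.235 (0.278). Genotype with TGF-β1 gave Col1a1 -0.095 (0.162), Col1a2 -0.152 (0.047), Krt18 -0.136 (0.047), Mki67 -0.124 (0.061) and Trib3 -0.067 (0.178), and the interaction Col1a1 -0.175 (0.059). Normexp gave interactions of 0.232 for Inmt (-1.407) and 0.245 for Sftpc (-1.471). The mean over probes gave Ide 0.15 (-0.017) for TGF-β1 in knockout and Ager -0.299 (0.177) for genotype with TGF-β1. In the authors' value table TGF-β1 in wild type gave Col3a1 -0.051, Plaur -0.164 and a shift of cholesterol synthesis of 0.276 (-0.351), and in knockout Plin2 -0.232. That cholesterol shift did not pass in the value table (adjusted p = 0.766 with camera). Genotype gave Igf2 0.301 (-0.433) and Prc1 -0.005 (0.146) with vehicle, and Ager -0.372 and Trib3 -0.067 with TGF-β1.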

Other observations

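The tests of X-linked copies, of female cells and of gene order were chosen only after the result was seen.

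Several list members went separate ways within their lists. Among pericyte markers the proteoglycan Cspg4 stood at -0.06 ± 0.10 with TGF-β1 in wild type cells and rose 3.05 ± 0.10 in knockout cells. The endothelial phosphatase Ptprb did likewise, at 0.09 ± 0.05 and 2.30 ± 0.05, while von Willebrand factor (Vwf) fell in both. Among Wnt ligands Wnt4 rose 0.90 ± 0.05 in wild type and fell by 1.18 ± 0.05 in knockout cells, while Wnt5a rose 0.79 ± 0.04 in knockout cells and in wild type cells stood at -0.40 ± 0.04 on its brightest probe and -0.11 on another. Nox4, which makes hydrogen peroxide, rose 1.82 ± 0.05 in knockout cells and in wild type cells stood at 0.56 ± 0.05 on its brightest probe but 0.08 on another. The interaction of Cspg4, Ptprb, Wnt4 and Wnt5a had adjusted p of 1.45e-10, 7.19e-12, 5.62e-12 and 1.82e-10, and that of Nox4 6.68e-10.

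Y-linked genes were well above background on all 16 arrays, although the arrays are labelled female. Probes of Y-linked genes reading the X-linked copies would follow those copies. Of the 4 genes 2 differed from their copy by more than 3 standard errors with TGF-β1 in knockout cells. Kdm5d stood at -0.30 (-0.35 on a dimmer probe) against 0.33 for Kdm5c (z = -7.16). Eif2s3y stood at 0.125 against 0.413 for Eif2s3x (z = -3.73). These standard errors cover only the spread between arrays. Different probes of 1 gene can lie further apart, 18 of 95 genes by at least 1 log2 unit in a comparison. The test therefore cannot exclude such reading. Female cells as labelled, without male ones, would hold no Y-linked RNA. The 4 genes, well above background on all arrays, argue against them only if their probes do not read the X-linked copies. The single Xist probe, well above background on 0 arrays, may be silent for its own reasons and decides nothing. Cells of male mice, or of both sexes pooled, could give these values, and the labels name no animal.

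Genes at least 2-fold different between genotypes with vehicle, 47 without Islr, were placed in the reference order. DNA carried along with the Islr deletion would put them near Islr, but 1 of 47 lay within 100 tested genes of it (Cilp, 65 genes away, -1.07 ± 0.24), so it does not account for the group. Differing DNA segments elsewhere in the genome could account for part, since 12 genes lay within 5 tested genes of another one changed in the same direction, against at most 9 in 10000 random sets of as many genes (95th percentile 4). They were Plac9a, Tmem254a, Tmem254c and Duxbl2, Ces2b and Ces2c, Gm16867 and Gm31896, Wfdc6b and Wfdc10, and B3gnt7 and 2810459M11Rik, named after their values were seen. Random sets leave out any likeness between neighbouring genes, so this excess alone cannot single out differing DNA. Probes shared by near-identical gene copies do not explain all of it, because 5 of 38 genes stayed near another with 1 gene kept per name stem (95th percentile 2 in random sets, highest 8).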
